A study of Mus musculus with 12 samples.

How the data were processed

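CD8 T cells were isolated by fluorescence-activated sorting into lysis buffer and their RNA was amplified with a SMART-Seq v4 kit for ultra-low input, per the labels' protocols. The 12 libraries form 4 groups of 3, taken from the sample labels. The kit adds no molecular identifiers, so PCR copies count as separate reads, and the intervals and floors given here cover counting error only. Reads were checked with FastQC 0.11.2, aligned with STAR 2.5.3a to the mm10 build and counted with featureCounts of the Subread package, and edgeR was used, per the submitters' processing notes. The gene annotation, the strand setting and the filters of that step are not given in the sources used here.

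The authors deposited 1 table of 23937 genes, whose signal is gene counts per-million reads (CPM) of a scaled library size. Its columns summed to 1344470 to 2086823 in low and 526580.2 to 880022 in high background libraries (split below). Scaling factors on library size, of geometric mean 1, raised the former. Within each column every value was a whole multiple of what 1 read is worth, so the reads were recovered, with 100% of values whole to within 1e-06 reads. Depth ran from 1104490 to 21014171 reads. At 3 reads, the limit that a count of 0 allows, a library's floor lay between 0.298 and 1.65 CPM. No 2 libraries held near-identical counts, with at most 3.61% of genes at equal counts.

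Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend, on all 12 libraries so that the groups share 1 estimate of the spread. The 22352 genes with at least 1 CPM in at least 3 libraries were tested and 1585 were not. Two-sided p-values were adjusted by Benjamini and Hochberg within each of 6 comparisons (threshold 0.05). Data were simulated for day 3 against naive brain (21450 genes). There limma called 5% of 100 changed by 2 (log2), 41% of 100 by 4, and 1 unchanged gene. DESeq2 called 15%, 69% and 61. With day 30 instead limma called 7 unchanged. The median log2 difference over all tested genes was 0.50, 0.19, -0.15, -0.37, 0.03 and -0.05 in the order day 3 and day 30 against naive brain, day 30 against day 3, and naive brain, day 3 and day 30 against blood. In the same order it was 1.13, 0.57, -0.45, -1.05, -0.06 and -0.44 with unscaled CPM, -0.555, -0.65, 0.07, 0.90, 0.24 and 0.37 with median centring, 0.02, 0.06, 0.02, -0.14, -0.12 and -0.06 with quantile normalization and 1.03, 0.45, -0.32, -1.02, -0.07 and -0.31 by DESeq2.

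Of 29 gene lists fixed before the data were examined, 27 were tested by camera against other genes. The correlation was preset (0.01) and then estimated, with adjustment over lists within a comparison. The lists share few genes, with 4 of 24 cytokine and chemokine genes, 3 of 22 cytotoxic effector genes and 1 of 18 microglia genes also in another list. The mitochondrial transcript list had too few members in the table, and the sex-linked list was kept as values per library. Each comparison names up to 10 genes per direction, or 5 in the comparisons of day 3 and day 30 with blood, by the largest log2 difference. Such genes passed the threshold, had a mean of at least 10 CPM in the higher group and 3 libraries all above the other 3, and were no predicted loci, receptor segments or pseudogenes. Up to 4 members were named from a list. Genes reached only through an overlap in position, and the shared genes lower at both times, were named after their values were seen. The groups, the comparisons, the tests, the lists, this rule and all alternatives except those listed as added were chosen before the data were examined. The plan took the values for CPM, and the scaled signal was tested in the same way.

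Of 187 named symbols, 182 were located in the GENCODE annotation vM21 of the same build, and 3 listed symbols were found under an older name. Among the 22352 tested genes, 121 had the same counts in every library as another gene, including 17 of 1696 called between naive brain and blood, 10 of 160 between day 3 and naive brain and 8 of 57 between day 30 and day 3, and their reads may belong to either copy.

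Libraries were split after the data were seen into 5 of low and 7 of high background, below and above an unscaled CPM of 1336 on 1502 olfactory, vomeronasal and taste receptor genes. The first principal component held 37.2% of the variance and followed this split, and the second 10.9%. Replicate numbers come from the labels. For day 30 and day 3, the deviations of same-numbered libraries from their group means correlated across genes at 0.530, 0.284 and 0.165, all above 0.1, and were taken as paired. Replicates 3 of day 30 and day 3 correlated better with the other group's replicate 2 (0.180 and 0.214). Pairing cannot be told from the background split. In the other comparisons the numbers did not pair the libraries.

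The alternatives were a pseudocount of 0.1 or 5, no filter or a stricter filter on low values, median centring, quantile normalization, limma's library quality weights, a robust spread estimate, a replicate block, an estimated correlation, each library left out in turn, fits on the 2 groups compared alone, an absolute log2 difference of at least 1 as well, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Added after the data were seen were the library background as a term, fits on the low or the high background libraries alone, CPM of the recovered reads without the deposited scaling factors (unscaled CPM), a block within day 3 and day 30 only for their comparison, and the estimated correlation together with the background term. Means of lists in these added fits, where said to be relative to all genes, have the mean of all tested genes subtracted.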

Results

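RNA was sequenced from CD8 T cells, the T cells that kill infected or damaged cells, sorted by flow cytometry from the brains of mice 3 and 30 days after stroke, from the brains of naive mice and from naive blood. There were 12 libraries, 3 in each of 4 groups: naive blood, naive brain, day 3 brain and day 30 brain. The protocol text speaks of spleens while the sample labels give brain or blood, and the groups here follow the sample labels. Nothing in the labels says that the 3 samples of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. The libraries held 1445036, 1104490 and 2141262 reads in naive blood replicates 1 to 3, 3469973, 14884783 and 21014171 in naive brain, 5094462, 1157538 and 1267597 at day 3 and 6844661, 1723245 and 1948611 at day 30. Expression is given in CPM (counts per-million reads of a scaled library size) as mean ± SD over 3 libraries, and differences as log2(CPM + 1) of the first group minus the second ± SE, which understates the change of genes with low values.

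Transcripts of the sorted cell type were present in every library. Cd8a, which encodes a chain of the CD8 co-receptor, measured 52.8 to 2809 CPM, Cd3e, a chain of the T cell receptor complex, 27.8 to 2370.1 CPM, and Ptprc, the leukocyte marker CD45, 232 to 2099 CPM. Cd4, the co-receptor of helper T cells, measured 0.906 to 26.8 CPM. Genes typical of microglia, the resident macrophages of the brain, took 2.24% to 5.32% of the reads in naive brain, 0.823% to 3.17% at day 3, 0.673% to 1.33% at day 30 and 0.0732% to 0.109% in blood. The libraries also differed in reads on olfactory, vomeronasal and taste receptor genes, which T cells are not known to use. As CPM without scaling factors (unscaled CPM), they came to 881, 196 and 164 in naive brain replicates 1 to 3, 254, 7903 and 4718 at day 3, 524, 3206 and 2026 at day 30 and 3286, 5526 and 4677 in blood. The 5 libraries with fewer such reads were the 3 of naive brain, day 3 replicate 1 and day 30 replicate 1, called low background here, and the other 7 are called high background.

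**Figure D1:**
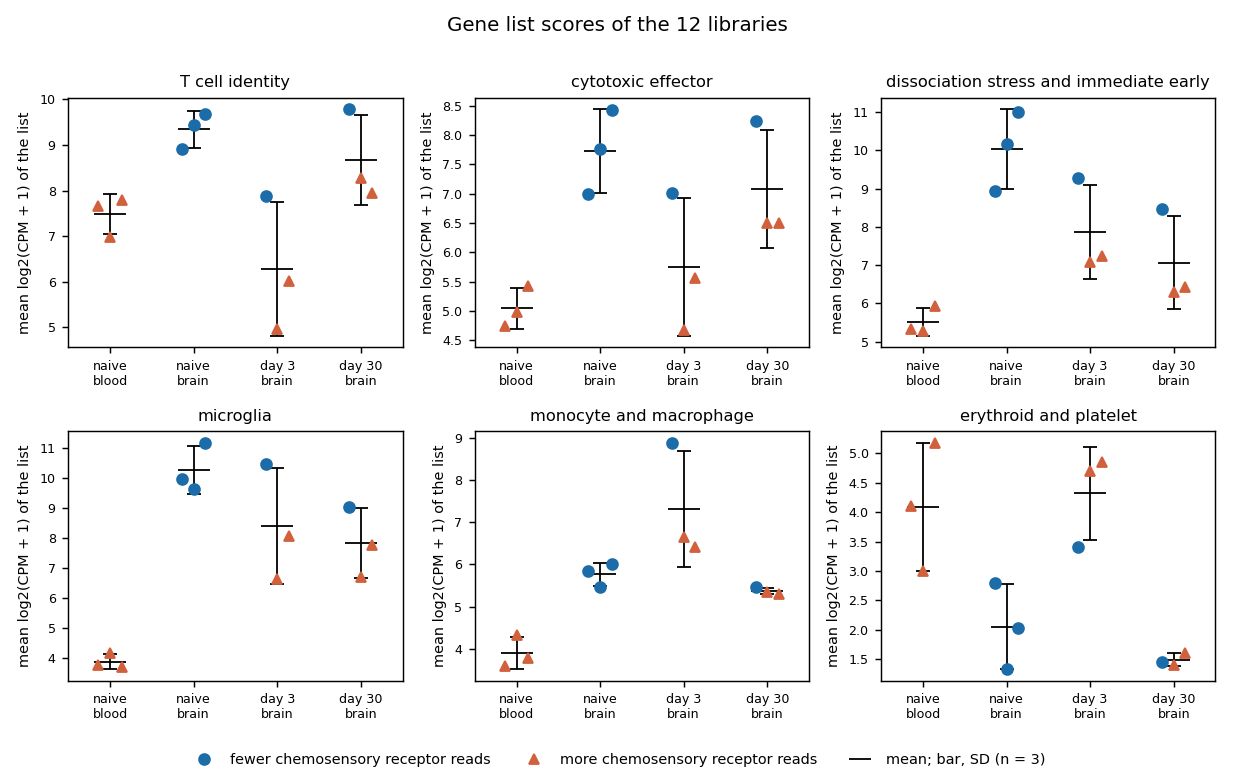
Mean log2(CPM + 1) per library over the genes of 6 lists, by group. Circles are libraries with fewer and triangles with more chemosensory receptor reads, the line is the group mean and the bar the SD (n = 3). The T cell identity score averaged 9.34 ± 0.40 in naive brain and 6.28 ± 1.47 at day 3, and the microglia score 10.25 ± 0.81 and 3.89 ± 0.26 in naive brain and naive blood.

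Day 3 brain was compared with naive brain. Spp1, which encodes the secreted phosphoprotein osteopontin, rose to 3756 ± 5124 CPM from 6.10 ± 6.05 CPM (log2 difference 8.48 ± 0.95, adjusted p = 1.17e-08). Thbs1 and Fn1, which encode the matrix proteins thrombospondin 1 and fibronectin, rose by 6.51 ± 1.03 and 5.46 ± 0.95, and the interferon-induced membrane protein genes Ifitm1 and Ifitm2 by 6.47 ± 1.15 and 5.49 ± 1.05 (adjusted p from 0.000262 to 0.00278). Apoc2, an apolipoprotein, Wfdc17, Cd24a and Chil3, a chitinase-like protein of macrophages, rose by 6.76 ± 1.20, 6.02 ± 1.04, 5.32 ± 1.16 and 5.48 ± 1.11. The chemokine receptor gene Ccr1 had 604 reads at day 3 and 2 in naive brain (adjusted p = 0.00672). Lck, the kinase that starts T cell receptor signalling, fell to 134 ± 178 CPM from 1938 ± 798 CPM (-4.71 ± 0.75, adjusted p = 0.000262). The adhesion receptor gene Cd2 changed by -4.81 ± 0.81, the co-stimulatory receptor gene Cd27 by -4.30 ± 0.82, the chemokine gene Xcl1 by -4.29 ± 0.93, and Cish and Gimap1, a cytokine signalling suppressor and a lymphocyte GTPase, by -4.23 ± 0.90 and -4.22 ± 0.86.

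Of 18 T cell identity genes, 0 rose and 13 fell (0 and 17 adjusted within the list alone). T cell identity genes averaged -3.06 (camera adjusted p = 1.36e-29, adjusted p = 0.144 with estimated correlation). Among them Cd3e changed by -3.95 ± 0.81 and Lat, an adaptor of receptor signalling, by -3.95 ± 0.74, while Cd8a and Cd8b1 changed by -2.76 ± 0.70 and -2.89 ± 0.71. Of 22 cytotoxic effector genes, 0 rose and 5 fell (0 and 12 within the list), averaging -1.97 (camera adjusted p = 4.41e-13, adjusted p = 0.144 with estimated correlation). The members Nkg7, a granule membrane protein gene, and Ccl5 changed by -3.90 ± 0.69 and -3.82 ± 0.68, and Ifng, which encodes interferon gamma, by -4.12 ± 0.94. Of 19 tissue-resident memory genes, 0 rose and 3 fell (0 and 3 within the list), namely Cxcr6, a chemokine receptor of tissue-resident cells, with -4.09 ± 0.79, Inpp4b and Xcl1. Tissue-resident memory genes averaged -1.19 (camera adjusted p = 7.48e-06, adjusted p = 0.197 with estimated correlation). Of 18 naive and recirculating T cell genes, 0 rose and 1 fell (0 and 9 within the list), averaging -1.81 (camera adjusted p = 4.04e-12, adjusted p = 0.144 with estimated correlation). Of 16 inhibitory receptor and exhaustion genes, 1 rose and 2 fell (1 and 6 within the list), with Tigit and Tox lower and Cd200 higher. Inhibitory receptor and exhaustion genes averaged -1.23 (camera adjusted p = 5.42e-05, adjusted p = 0.144 with estimated correlation). Of 21 dissociation stress and immediate early genes, transcripts that tissue handling can induce, 0 rose and 3 fell (0 and 15 within the list), led by Junb with -3.22 ± 0.75 and Egr1 with -3.19 ± 0.76. Dissociation stress and immediate early genes averaged -2.18 (camera adjusted p = 2.58e-17, adjusted p = 0.144 with estimated correlation).

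Genes of other cell types moved in both directions at day 3. Of 18 microglia genes, 0 rose and 2 fell (0 and 10 within the list), with Tmem119 at -4.03 ± 0.89 and Cst3 at -3.10 ± 0.67. Microglia genes averaged -1.86 (camera adjusted p = 2.31e-11, adjusted p = 0.179 with estimated correlation), and day 3 replicate 1 scored 10.46 against a naive brain mean of 10.25 ± 0.81. Of 19 monocyte and macrophage genes, 2 rose and 0 fell (7 and 1 within the list), averaging 1.55 (camera adjusted p = 0.00166, adjusted p = 0.308 with estimated correlation), and they took 0.602% to 2.53% of the reads at day 3 against 0.352% to 0.523% in naive brain. Of 23 extracellular matrix and wound repair genes, 2 rose and 0 fell (6 and 1 within the list), averaging 1.63 (camera adjusted p = 0.000285, adjusted p = 0.144 with estimated correlation). Of 13 erythroid and platelet genes, 4 rose and 0 fell (6 and 0 within the list), all of them haemoglobin genes such as Hba-a1 with 5.16 ± 1.01, whose counts equal those of Hba-a2. Erythroid and platelet genes averaged 2.27 (camera adjusted p = 1.26e-05, adjusted p = 0.144 with estimated correlation). Camera also called the T cell receptor activation, homing and adhesion receptors, glycolysis and hypoxia, oxidative phosphorylation, neutrophil and neuron lists. Their mean differences were -1.01 to 1.61 (adjusted p = 8.57e-07 to 0.0149, adjusted p = 0.151 to 0.534 with an estimated correlation). Of these lists, the mean of oxidative phosphorylation turned to 0.05 with quantile normalization, and those of T cell receptor activation and glycolysis and hypoxia to 0.22 and 0.23 with unscaled CPM. The proliferation, type I interferon response, cytokines and chemokines, cholesterol synthesis, B cell, CD4 and regulatory T cell, natural killer cell, dendritic cell and MHC class II, endothelial and mural, astrocyte and oligodendrocyte lineage lists did not pass (camera adjusted p = 0.0887 to 0.913). For CD4 and regulatory T cell and natural killer cell genes the mean and the test differed in sign, as did mean and median for cytokines and chemokines.

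In all, limma called 34 genes higher and 126 lower at day 3 among 22352 tested. The count was 56 (25 higher and 31 lower) with quantile normalization, 225 (115 higher and 110 lower) with unscaled CPM, 5 (1 higher and 4 lower) with median centring, 1000 (822 higher and 178 lower) by DESeq2 and 17 (16 higher and 1 lower) by edgeR. It was 44 with a pseudocount of 0.1, 45 with no filter and 2104 with library quality weights. Leaving out single libraries gave 22 without naive brain 2, 23 without day 3 brain 2, 36 without day 3 brain 3, 37 without naive brain 3, 267 without day 30 brain 1, 666 without day 3 brain 1. With library background as a term in the model 5 (5 higher and 0 lower) were called, and 0 among the low background libraries alone, where day 3 has 1 library. With the term, the T cell identity score differed by -1.71 ± 0.46 (camera: adjusted p = 0.0419 with estimated correlation). Relative to all genes, the type I interferon response, dendritic cell and MHC class II and cholesterol synthesis lists were higher with it (1.08, adjusted p = 0.000229, 1.26, adjusted p = 1.18e-05 and 0.76, adjusted p = 0.00662, but adjusted p = 0.128 to 0.199 with an estimated correlation), and the tissue-resident memory, T cell receptor activation, glycolysis and hypoxia, oxidative phosphorylation, microglia and neuron lists no longer passed (adjusted p = 0.115 to 0.914). Day 3 replicate 1 scored 6.97 on type I interferon response and 8.80 on dendritic cell and MHC class II genes, against 4.39 to 4.71 and 6.22 to 6.57 in the other day 3 libraries and 5.11 to 5.98 and 6.13 to 6.61 in naive brain. In the GENCODE annotation of the mm10 build, Spp1 lies on chromosome 5 at 104435118 to 104441050 and Thbs1 on chromosome 2 at 118111876 to 118127133. Of the genes that fell, Lck lies on chromosome 4 at 129548344 to 129573641. Spp1 overlaps the predicted gene Gm42793 and Thbs1 overlaps Gm29233, and without strand their reads cannot be separated.

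The comparison of day 30 brain with naive brain asks what differs once the injury is a month old. Jun, a subunit of the transcription factor AP-1, fell to 270.4 ± 325 CPM from 7210.5 ± 4927 CPM (-5.16 ± 0.73, adjusted p = 2.45e-05), and Fos, its partner, to 679.8 ± 684 CPM from 10112 ± 6554 CPM (-4.19 ± 0.71, adjusted p = 0.00186). The heat shock genes Hspb1 and Hspa1a changed by -5.14 ± 1.17 and -4.80 ± 1.08, with Hspb1 at 563 CPM in naive brain 3 and 16.3 and 25.6 CPM in the others. Also lower were H2-DMb1, which helps load peptide on MHC class II, at -4.90 ± 1.04, Irf5, a transcription factor of inflammatory responses, at -4.72 ± 0.98, and Slamf9 and Tbxas1, the thromboxane synthase gene, at -4.75 ± 1.002 and -4.74 ± 1.01 (adjusted p from 0.0289 to 0.0371 for these genes and the heat shock genes).

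Of 21 dissociation stress and immediate early genes, 0 rose and 10 fell (0 and 19 within the list), averaging -2.97 (camera adjusted p = 7.93e-35, adjusted p = 0.109 with estimated correlation). These genes took 0.3995% to 1.06% of the reads at day 30 and 1.84% to 3.92% in naive brain. Of 18 microglia genes, 0 rose and 4 fell (0 and 12 within the list), with Tmem119 at -4.07 ± 0.89, C1qa, a subunit of complement C1q, at -3.96 ± 0.87 and Fcrls at -3.83 ± 0.86. Microglia genes averaged -2.43 (camera adjusted p = 1.77e-21, adjusted p = 0.153 with estimated correlation). Of 17 dendritic cell and MHC class II genes, 0 rose and 3 fell (1 and 7 within the list), with H2-Ab1, an MHC class II chain, at -4.15 ± 0.76. Dendritic cell and MHC class II genes averaged -1.85 (camera adjusted p = 1.43e-10, adjusted p = 0.109 with estimated correlation). Of 18 T cell identity genes, 0 rose and 0 fell (0 and 0 within the list), and Cd8a measured 1364 ± 1257 CPM against 1242 ± 399.5 CPM. T cell identity genes averaged -0.67 (camera adjusted p = 0.00621, adjusted p = 0.652 with estimated correlation), which turned to 0.09 with quantile normalization and 0.01 with unscaled CPM. Of 22 cytotoxic effector genes, 0 rose and 0 fell (0 and 0 within the list), averaging -0.64 (camera adjusted p = 0.0256, adjusted p = 0.652 with estimated correlation), and relative to all genes -0.08, adjusted p = 0.534 with quantile normalization. Of 24 cytokine and chemokine genes, 0 rose and 1 fell (0 and 3 within the list), averaging -0.68 (camera adjusted p = 0.00621, adjusted p = 0.525 with estimated correlation), with the neutrophil chemokine gene Cxcl2 at -4.66 ± 0.99. Of 16 neuron genes, 0 rose and 0 fell (0 and 0 within the list), averaging 1.31 (camera adjusted p = 0.00317, adjusted p = 0.652 with estimated correlation), and they took at most 0.0238% of the reads in any day 30 library. Camera called the naive and recirculating T cell, T cell receptor activation, proliferation, homing and adhesion receptors, glycolysis and hypoxia, oxidative phosphorylation and cholesterol synthesis lists lower. Their mean differences were -0.96 to -0.43 (adjusted p = 0.000203 to 0.0326, adjusted p = 0.525 to 0.747 with an estimated correlation). The mean of oxidative phosphorylation turned to 0.25 with quantile normalization and 0.25 with unscaled CPM and that of T cell receptor activation to 0.03 with unscaled CPM. Proliferation turned to 0.16, adjusted p = 0.741 relative to all genes without naive brain 3. The tissue-resident memory, inhibitory receptor and exhaustion, type I interferon response, extracellular matrix and wound repair, monocyte and macrophage, neutrophil, B cell, CD4 and regulatory T cell, natural killer cell, endothelial and mural, astrocyte, oligodendrocyte lineage and erythroid and platelet lists did not pass (camera adjusted p = 0.0527 to 0.910).

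In all, limma called 0 genes higher and 50 lower at day 30, against 656 higher and 1334 lower at an unadjusted p under 0.05. The count was 6 (0 higher and 6 lower) by edgeR, 240 (168 higher and 72 lower) by DESeq2, 12 (4 higher and 8 lower) with quantile normalization, 119 (29 higher and 90 lower) with unscaled CPM and 2 (0 higher and 2 lower) with median centring. It was 0 in a fit on the 2 groups alone, 2 with a pseudocount of 0.1, 1 with no filter, 5 with a stricter filter and 256 with library quality weights. Leaving out single libraries gave 1 without day 30 brain 2, 2 without naive brain 3, 3 without naive brain 2, 5 without day 30 brain 3, 11 without naive brain 1, 532 without day 30 brain 1. With the library background term 0 were called, and 0 in the low background libraries alone, where day 30 has 1 library. With the term, the stress list score differed by -1.56 ± 0.59 (camera: adjusted p = 0.169 with estimated correlation). Relative to all genes, 4 lists turned higher at day 30 with it by camera at the preset correlation, namely T cell identity (0.67, adjusted p = 1.79e-05), cytotoxic effector (0.56, adjusted p = 0.000610), tissue-resident memory (0.72, adjusted p = 0.00182) and oxidative phosphorylation (0.57, adjusted p = 0.000439). The type I interferon response list was higher (1.57, adjusted p = 7.52e-11) and erythroid and platelet lower (-1.04, adjusted p = 0.00344) with it, but none of these 6 passed with it and an estimated correlation (adjusted p = 0.0749 to 0.635). Day 30 replicate 1 scored 6.80 on type I interferon response, 9.78 on T cell identity and 8.24 on cytotoxic effector genes, against 4.90 to 5.38, 7.94 to 8.28 and 6.490 to 6.505 in the other day 30 libraries and 5.11 to 5.98, 8.91 to 9.68 and 6.99 to 8.42 in naive brain. With the term the naive and recirculating T cell, T cell receptor activation, proliferation, homing and adhesion receptors, cytokines and chemokines, glycolysis and hypoxia, cholesterol synthesis and neuron lists no longer passed (adjusted p = 0.721 to 0.974). By position, Jun lies on chromosome 4 at 95049034 to 95052222. It overlaps the antisense gene Junos.

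Day 30 brain was compared with day 3 brain. Cxcr6 rose to 1551 ± 1819 CPM from 96.9 ± 102 CPM (4.09 ± 0.79, adjusted p = 0.00315), and Sh2d1a, the adaptor of SLAM family receptors, to 224 ± 67.1 CPM from 15.9 ± 15.4 CPM (4.36 ± 0.81, adjusted p = 0.00190). Klrc1, which encodes the inhibitory receptor NKG2A, Klra23, a Ly49 family receptor, and Fasl, the death ligand, rose by 3.85 ± 0.84, 3.83 ± 0.85 and 3.76 ± 0.87, and Xcl1, Cd27 and Ms4a4b by 3.96 ± 0.93, 3.78 ± 0.82 and 3.76 ± 0.67. Ifitm1 fell to 1.52 ± 1.38 CPM from 624 ± 618 CPM (-7.70 ± 1.15, adjusted p = 2.34e-05), Cxcl2 changed by -6.98 ± 0.99, and Apoc2 and Thbs1 by -6.24 ± 1.20 and -6.04 ± 1.03. The haemoglobin genes Hba-a1 and Hba-a2, of equal counts, changed by -7.10 ± 1.01, and Hbb-bs and Hbb-b1, also of equal counts, by -6.88 ± 1.002.

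Of 18 T cell identity genes, 3 rose and 0 fell (16 and 0 within the list), with Lck at 3.35 ± 0.75, Cd2 at 3.48 ± 0.81 and Cd3g, a chain of the receptor complex, at 3.25 ± 0.70. T cell identity genes averaged 2.38 (camera adjusted p = 1.34e-32, adjusted p = 0.0450 with estimated correlation). Cd8a measured 1364 ± 1257 CPM at day 30 and 253 ± 234 CPM at day 3 (adjusted p = 0.107). With the replicate number as a block Cd8a and Cd3e passed (adjusted p = 0.0111 and 0.0136). Of 22 cytotoxic effector genes, 3 rose and 0 fell (8 and 0 within the list), with Nkg7 at 3.54 ± 0.69. Cytotoxic effector genes averaged 1.33 (camera adjusted p = 3.97e-12, adjusted p = 0.112 with estimated correlation). Of 19 tissue-resident memory genes, 3 rose and 0 fell (3 and 0 within the list), namely Cxcr6, Xcl1 and Inpp4b. Tissue-resident memory genes averaged 0.97 (camera adjusted p = 5.15e-06, adjusted p = 0.207 with estimated correlation). Of 18 naive and recirculating T cell genes, 2 rose and 0 fell (6 and 0 within the list), averaging 0.99 (camera adjusted p = 3.16e-07, adjusted p = 0.207 with estimated correlation). Of 19 monocyte and macrophage genes, 0 rose and 1 fell (0 and 7 within the list), namely Spp1 with -4.96 ± 0.95. Monocyte and macrophage genes averaged -1.95 (camera adjusted p = 3.89e-12, adjusted p = 0.0450 with estimated correlation). Of 17 dendritic cell and MHC class II genes, 0 rose and 4 fell (0 and 13 within the list), with H2-Ab1 at -4.34 ± 0.76 and H2-Eb1 at -4.20 ± 0.83. Dendritic cell and MHC class II genes averaged -2.62 (camera adjusted p = 1.77e-20, adjusted p = 0.0244 with estimated correlation). Of 23 extracellular matrix and wound repair genes, 0 rose and 2 fell (0 and 5 within the list), namely Thbs1 and Tgfbi. Extracellular matrix and wound repair genes averaged -1.34 (camera adjusted p = 3.42e-06, adjusted p = 0.0275 with estimated correlation). Of 13 erythroid and platelet genes, 0 rose and 4 fell (0 and 4 within the list), averaging -2.83 (camera adjusted p = 1.70e-13, adjusted p = 0.0244 with estimated correlation). Of 24 cytokine and chemokine genes, 1 rose and 2 fell (3 and 4 within the list), with Xcl1 higher and Cxcl2 and Il1b lower, and camera did not call the list (adjusted p = 0.314). Of 18 microglia genes, 0 rose and 0 fell (0 and 0 within the list), averaging -0.56 (camera adjusted p = 0.0447, adjusted p = 0.7002 with estimated correlation), and relative to all genes it turned to 0.77, adjusted p = 0.0347 without day 3 brain 1 and 0.21, adjusted p = 0.989 in the high background libraries alone. Of 21 dissociation stress and immediate early genes, 0 rose and 0 fell (0 and 0 within the list), averaging -0.80 (camera adjusted p = 0.00198, adjusted p = 0.594 with estimated correlation), and 0.21, adjusted p = 0.492 relative to all genes without day 3 brain 1. Of 12 B cell genes, 0 rose and 1 fell (0 and 2 within the list), averaging -0.99 (camera adjusted p = 0.0383, adjusted p = 0.294 with estimated correlation), with the lymphocyte surface gene Ly6d at -4.89 ± 0.97. Camera called the inhibitory receptor and exhaustion, type I interferon response, oxidative phosphorylation, cholesterol synthesis and neutrophil lists. Their mean differences were -1.15 to 0.76 (adjusted p = 0.000168 to 0.0358, adjusted p = 0.207 to 0.617 with an estimated correlation). The T cell receptor activation, proliferation, homing and adhesion receptors, glycolysis and hypoxia, CD4 and regulatory T cell, natural killer cell, endothelial and mural, neuron, astrocyte and oligodendrocyte lineage lists did not pass (camera adjusted p = 0.116 to 0.959). Relative to all genes, type I interferon response turned to -0.0503, adjusted p = 0.978 without day 3 brain 2, and glycolysis and hypoxia to 0.65, adjusted p = 0.0347 without day 3 brain 1. In T cell receptor activation mean and median, and in neuron mean and test, differed in sign.

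In all, limma called 26 genes higher and 31 lower at day 30 than at day 3. Same-numbered libraries deviated together here, as did background classes. With the replicate number as a block the counts were 115 (61 higher and 54 lower) over all libraries and 146 (87 higher and 59 lower) within these 2 groups alone, where the B cell list no longer passed (adjusted p = 0.0530). The count was 8 (0 higher and 8 lower) with median centring, 134 (63 higher and 71 lower) with quantile normalization, 265 (112 higher and 153 lower) with unscaled CPM, 35 (7 higher and 28 lower) by edgeR and 167 (49 higher and 118 lower) by DESeq2. It was 91 in a fit on the 2 groups alone, 31 with a pseudocount of 0.1, 24 with no filter and 97 with library quality weights. Without single libraries it was 26 without day 3 brain 2, 37 without day 3 brain 3, 115 without day 3 brain 1. With the library background term 140 (83 higher and 57 lower) were called, and 15 (10 higher and 5 lower) in the high background libraries alone. The B cell list no longer passed (adjusted p = 0.0669) with the term, nor the microglia, neutrophil and B cell lists (adjusted p = 0.0817 to 0.989) in the high background libraries, and extracellular matrix and wound repair did not pass with the term and an estimated correlation (adjusted p = 0.0547). By position, Cxcr6 lies on chromosome 9 at 123806475 to 123811760. Cxcr6 overlaps Fyco1 and Sh2d1a Tenm1.

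The 2 stroke groups shared 7 genes lower than in naive brain: Jun and Junb, subunits of AP-1, the microglial genes Tmem119 and Cx3cr1, the lens crystallin gene Crybb1, the histone gene Hist1h3d, and Glul, the glutamine synthetase gene. No gene was higher at both times by limma, since 0 passed at day 30. Independent lists of the same sizes would share 0.282 lower genes. Unchanged groups simulated against the same naive brain libraries shared 8.13 on average and at most 15 among lists of the same sizes, so the shared controls alone can give an overlap of this size. The overlap was 127 (119 higher and 8 lower) by DESeq2, 0 by edgeR, 4 (1 higher and 3 lower) with quantile normalization, 19 (4 higher and 15 lower) with unscaled CPM and 0 with the library background term. Leaving out single libraries gave 0 without day 3 brain 2, 0 without day 3 brain 3, 0 without naive brain 2, 0 without naive brain 3, 1 without day 30 brain 2, 1 without day 30 brain 3, 2 without naive brain 1, 11 without naive blood 2, 24 without day 3 brain 1, 59 without day 30 brain 1.

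**Figure D2:**
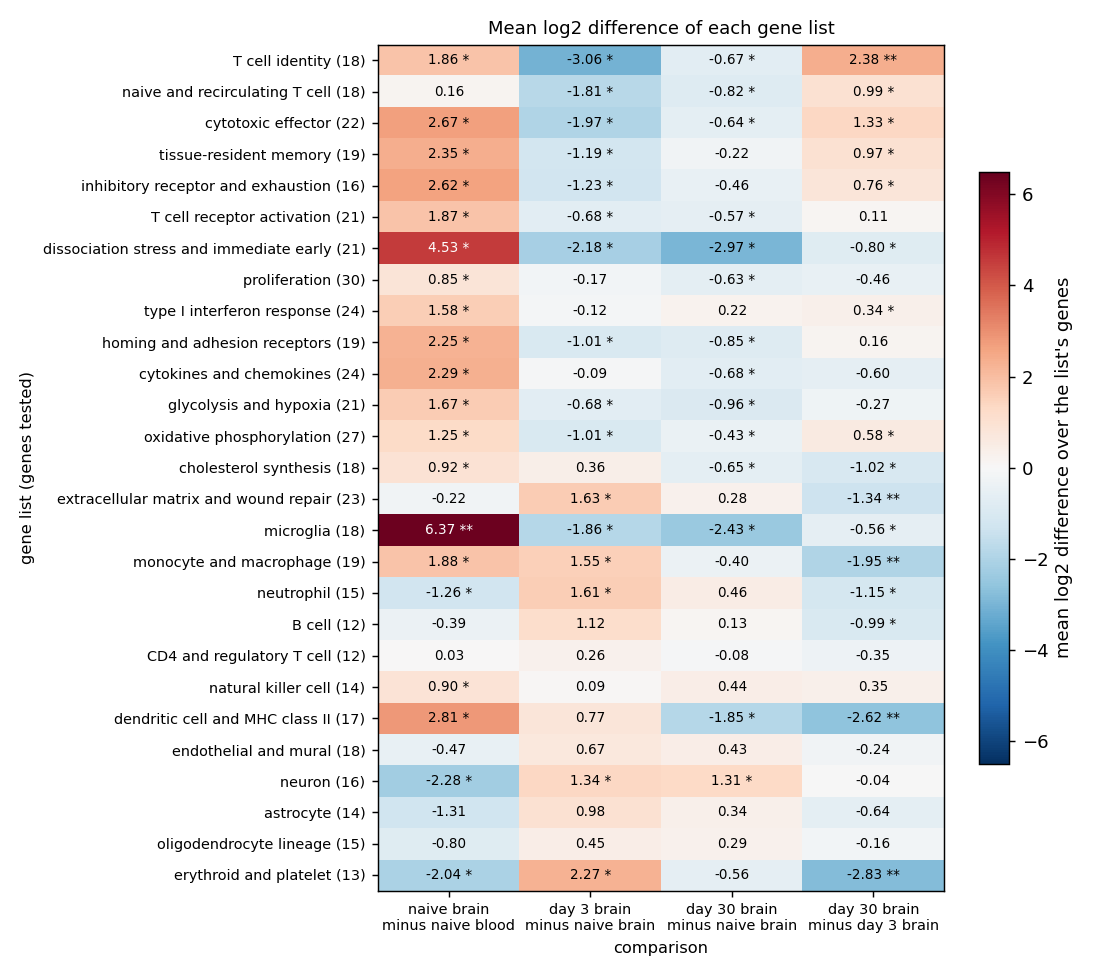
Mean log2 difference of 27 gene lists in 4 comparisons, first group minus second. A star marks a camera adjusted p under 0.05 and a double star one that also held with an estimated correlation. The T cell identity list averaged -3.06 in day 3 against naive brain and 2.38 in day 30 against day 3.

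Naive brain was compared with naive blood. Genes of microglia were higher in brain. C1qb, a subunit of complement C1q, measured 7139.9 ± 4725 CPM in brain and 17.8 ± 3.78 CPM in blood (8.40 ± 0.74, adjusted p = 8.36e-13), and C1qa, the purinergic receptor gene P2ry12, Siglech and Cx3cr1, the fractalkine receptor gene, rose by 8.31 ± 0.87, 7.64 ± 0.82, 7.21 ± 0.68 and 7.15 ± 0.82. Egr1, an immediate early transcription factor, rose by 7.82 ± 0.76, and Ly6a, the surface antigen Sca-1 of activated lymphocytes, to 643 ± 208 CPM from 2.57 ± 2.01 CPM (7.59 ± 0.75, adjusted p = 2.96e-11). Haemoglobin genes fell, with Hba-a1 and Hba-a2 at 8.81 ± 11.6 CPM in brain and 1025 ± 918 CPM in blood (-6.31 ± 1.01, adjusted p = 8.40e-06), Hbb-bs and Hbb-b1 at -5.40 ± 1.002 and Hbb-bt and Hbb-b2 at -5.01 ± 1.26, each pair of equal counts.

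Of 18 microglia genes, 18 rose and 0 fell (18 and 0 within the list), averaging 6.37 (camera adjusted p = 2.11e-48, adjusted p = 0.0499 with estimated correlation). Of 21 dissociation stress and immediate early genes, 17 rose and 0 fell (20 and 0 within the list), with Fos at 7.05 ± 0.71 and Atf3 at 6.69 ± 0.79. Dissociation stress and immediate early genes averaged 4.53 (camera adjusted p = 1.15e-32, adjusted p = 0.0505 with estimated correlation). Of 22 cytotoxic effector genes, 10 rose and 0 fell (15 and 0 within the list), with Gzmk, which encodes granzyme K, at 6.16 ± 0.86 and Ifng at 6.51 ± 0.94. Cytotoxic effector genes averaged 2.67 (camera adjusted p = 9.57e-12, adjusted p = 0.0869 with estimated correlation). Of 19 tissue-resident memory genes, 7 rose and 0 fell (9 and 0 within the list), with Xcl1 at 7.04 ± 0.93 and the transcription factor gene Bhlhe40 at 5.66 ± 0.77. Tissue-resident memory genes averaged 2.35 (camera adjusted p = 5.45e-09, adjusted p = 0.103 with estimated correlation). Of 16 inhibitory receptor and exhaustion genes, 7 rose and 0 fell (9 and 0 within the list), with Pdcd1, which encodes PD-1, at 5.02 ± 1.004, Tigit at 4.99 ± 0.97 and Ctla4 at 4.87 ± 0.89. Inhibitory receptor and exhaustion genes averaged 2.62 (camera adjusted p = 1.12e-08, adjusted p = 0.0505 with estimated correlation). Of 19 homing and adhesion receptor genes, 9 rose and 0 fell (12 and 1 within the list), with the chemokine receptor gene Cxcr3 at 6.56 ± 0.83. Homing and adhesion receptor genes averaged 2.25 (camera adjusted p = 5.01e-09, adjusted p = 0.0544 with estimated correlation). Of 24 cytokine and chemokine genes, 13 rose and 0 fell (14 and 1 within the list), with Ccl4 at 5.57 ± 0.69. Cytokine and chemokine genes averaged 2.29 (camera adjusted p = 5.01e-09, adjusted p = 0.0505 with estimated correlation). Of 18 T cell identity genes, 5 rose and 0 fell (10 and 0 within the list), with Cd3e at 4.09 ± 0.81 and Cd8a at 2.53 ± 0.70. T cell identity genes averaged 1.86 (camera adjusted p = 1.70e-07, adjusted p = 0.263 with estimated correlation). Of 21 T cell receptor activation genes, 10 rose and 0 fell (12 and 1 within the list), averaging 1.87 (camera adjusted p = 5.54e-07, adjusted p = 0.0741 with estimated correlation).

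Of 24 type I interferon response genes, 5 rose and 0 fell (11 and 0 within the list), with Bst2, which encodes tetherin, at 5.84 ± 0.80. Type I interferon response genes averaged 1.58 (camera adjusted p = 2.57e-05, adjusted p = 0.263 with estimated correlation). Of 19 monocyte and macrophage genes, 9 rose and 0 fell (10 and 3 within the list), averaging 1.88 (camera adjusted p = 1.92e-06, adjusted p = 0.120 with estimated correlation). Of 17 dendritic cell and MHC class II genes, 8 rose and 0 fell (10 and 0 within the list), with H2-Aa at 6.69 ± 0.83. Dendritic cell and MHC class II genes averaged 2.81 (camera adjusted p = 3.96e-10, adjusted p = 0.0505 with estimated correlation). Of 13 erythroid and platelet genes, 0 rose and 4 fell (1 and 4 within the list), averaging -2.04 (camera adjusted p = 0.000969, adjusted p = 0.181 with estimated correlation). Of 15 neutrophil genes, 1 rose and 1 fell (1 and 3 within the list), averaging -1.26 (camera adjusted p = 0.0364, adjusted p = 0.288 with estimated correlation), which turned to 0.00199 with median centring. Camera called the proliferation, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, natural killer cell and neuron lists. Their mean differences were -2.28 to 1.67 (adjusted p = 9.63e-06 to 0.0469, adjusted p = 0.224 to 0.550 with an estimated correlation). With quantile normalization the mean of oxidative phosphorylation turned to -0.02, and with unscaled CPM those of proliferation and cholesterol synthesis to -0.21 and -0.17. The naive and recirculating T cell, extracellular matrix and wound repair, B cell, CD4 and regulatory T cell, endothelial and mural, astrocyte and oligodendrocyte lineage lists did not pass (camera adjusted p = 0.0582 to 0.828). In extracellular matrix and wound repair the mean of -0.22 and the test differed in sign.

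In all, limma called 1478 genes higher and 218 lower in naive brain than in naive blood. The split moved to 2894 (2882 higher and 12 lower) after median centring, 704 (574 higher and 130 lower) after quantile normalization, 1563 (693 higher and 870 lower) with unscaled CPM, 4169 (2455 higher and 1714 lower) with library quality weights and 3842 (1328 higher and 2514 lower) by DESeq2. Leaving out single libraries gave 768 without naive brain 3, 906 without naive brain 2. Every naive brain library was of low and every naive blood library of high background, so no value within either class exists. With the library background term, which then rests on the stroke groups, 35 (35 higher and 0 lower) were called. With it the microglia score differed by 3.91 ± 0.85 (camera: adjusted p = 0.0280 with estimated correlation). Relative to all genes, the naive and recirculating T cell list, with a mean of 0.16 that did not pass (adjusted p = 0.662), was lower in brain with the term (-1.22, adjusted p = 1.20e-06, but adjusted p = 0.163 with an estimated correlation), quantile normalization (-1.13, adjusted p = 3.04e-05) and unscaled CPM (-0.11, adjusted p = 0.0291), and the T cell identity, proliferation, type I interferon response, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, neutrophil and neuron lists no longer passed (adjusted p = 0.156 to 0.981). By position, C1qb lies on chromosome 4 at 136880129 to 136886187.

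Day 3 brain was compared with naive blood. Spp1 measured 3756 ± 5124 CPM at day 3 and 3.44 ± 2.25 CPM in blood (8.80 ± 0.95, adjusted p = 7.30e-10). The MHC class II gene H2-Aa rose by 7.72 ± 0.83, Ly6d by 7.63 ± 0.97, Ifitm1 by 7.60 ± 1.15 and Ly6a by 7.37 ± 0.75. Dapl1 fell to 39.4 ± 40.3 CPM from 619 ± 311 CPM (-4.40 ± 0.76, adjusted p = 9.94e-05), and Lef1, a transcription factor of naive T cells, Txk, a Tec family kinase, Cd55, a complement regulator, and Scml4 changed by -3.67 ± 0.70, -3.46 ± 0.74, -3.87 ± 0.90 and -3.42 ± 0.78. Of 18 naive and recirculating T cell genes, 0 rose and 4 fell (0 and 8 within the list), averaging -1.65 (camera adjusted p = 2.64e-13, adjusted p = 0.0957 with estimated correlation). Of 18 T cell identity genes, 0 rose and 0 fell (0 and 3 within the list), averaging -1.19 (camera adjusted p = 2.39e-08, adjusted p = 0.237 with estimated correlation). Of 18 microglia genes, 15 rose and 0 fell (18 and 0 within the list), averaging 4.50 (camera adjusted p = 5.81e-59, adjusted p = 0.00901 with estimated correlation). Of 19 monocyte and macrophage genes, 10 rose and 0 fell (14 and 0 within the list), averaging 3.42 (camera adjusted p = 5.14e-30, adjusted p = 0.00683 with estimated correlation). Of 17 dendritic cell and MHC class II genes, 8 rose and 0 fell (12 and 0 within the list), averaging 3.58 (camera adjusted p = 8.65e-29, adjusted p = 0.00683 with estimated correlation). Of 24 cytokine and chemokine genes, 9 rose and 0 fell (12 and 0 within the list), with the chemokine genes Ccl2 at 5.90 ± 0.94 and Cxcl10 at 5.17 ± 1.06. Cytokine and chemokine genes averaged 2.20 (camera adjusted p = 3.63e-13, adjusted p = 0.0137 with estimated correlation). Of 23 extracellular matrix and wound repair genes, 6 rose and 0 fell (10 and 0 within the list), with Lgals3, which encodes galectin 3, at 5.40 ± 0.91. Extracellular matrix and wound repair genes averaged 1.41 (camera adjusted p = 1.32e-06, adjusted p = 0.0137 with estimated correlation). Of 21 dissociation stress and immediate early genes, 6 rose and 0 fell (14 and 0 within the list), averaging 2.35 (camera adjusted p = 1.18e-20, adjusted p = 0.0957 with estimated correlation). Of 19 homing and adhesion receptor genes, 4 rose and 0 fell (8 and 0 within the list), averaging 1.25 (camera adjusted p = 2.01e-05, adjusted p = 0.137 with estimated correlation). Of 24 type I interferon response genes, 1 rose and 0 fell (2 and 0 within the list), averaging 1.46 (camera adjusted p = 4.84e-06, adjusted p = 0.237 with estimated correlation).

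Camera called the tissue-resident memory, inhibitory receptor and exhaustion, T cell receptor activation, glycolysis and hypoxia, cholesterol synthesis, natural killer cell and neuron lists. Their mean differences were -0.94 to 1.39 (adjusted p = 6.35e-05 to 0.00708, adjusted p = 0.132 to 0.512 with an estimated correlation). The cytotoxic effector, proliferation, oxidative phosphorylation, neutrophil, B cell, CD4 and regulatory T cell, endothelial and mural, astrocyte, oligodendrocyte lineage and erythroid and platelet lists did not pass (camera adjusted p = 0.0505 to 0.970). Mean and median differed in sign for the B cell, CD4 and regulatory T cell, endothelial and mural and erythroid and platelet lists. In all, limma called 245 genes higher and 19 lower at day 3 than in blood. The count was 601 (452 higher and 149 lower) with quantile normalization, 573 (438 higher and 135 lower) with unscaled CPM, 75 (74 higher and 1 lower) with median centring and 575 (488 higher and 87 lower) by DESeq2. It was 139 without day 3 brain 1. With the library background term 220 (157 higher and 63 lower) were called, and 135 (87 higher and 48 lower) in the high background libraries alone. Relative to all genes, oxidative phosphorylation was lower with the term (-0.45, adjusted p = 0.0281, but adjusted p = 0.659 with an estimated correlation) and without day 3 brain 1 (-0.62, adjusted p = 0.00209), and with the term the tissue-resident memory, type I interferon response, glycolysis and hypoxia and neuron lists no longer passed (adjusted p = 0.0678 to 0.430). In the high background libraries alone these 4 lists and T cell receptor activation (0.44, adjusted p = 0.236) no longer passed.

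Day 30 brain was compared with naive blood. Ly6a measured 814 ± 612 CPM at day 30 and 2.57 ± 2.01 CPM in blood (7.69 ± 0.75, adjusted p = 8.63e-11). Xcl1, Gzmk, C1qb and P2ry12 rose by 6.71 ± 0.93, 6.21 ± 0.86, 5.69 ± 0.74 and 5.61 ± 0.82. Haemoglobin genes fell, with Hba-a1 and Hba-a2 at 0.530 ± 0.344 CPM at day 30 (-8.26 ± 1.01, adjusted p = 9.86e-08), from 4 reads there, and Hbb-bs and Hbb-b1 by -8.05 ± 1.002. Of 22 cytotoxic effector genes, 5 rose and 0 fell (12 and 0 within the list), with Klrc1 at 3.98 ± 0.84 and Ifng at 4.99 ± 0.94. Cytotoxic effector genes averaged 2.03 (camera adjusted p = 3.87e-14, adjusted p = 0.0579 with estimated correlation). Of 19 tissue-resident memory genes, 5 rose and 0 fell (8 and 0 within the list), with Cxcr6 at 3.61 ± 0.79. Tissue-resident memory genes averaged 2.13 (camera adjusted p = 2.66e-13, adjusted p = 0.0579 with estimated correlation). Of 16 inhibitory receptor and exhaustion genes, 5 rose and 0 fell (8 and 0 within the list), with Ctla4 at 4.52 ± 0.89 and Cd160 at 4.73 ± 0.95. Inhibitory receptor and exhaustion genes averaged 2.15 (camera adjusted p = 7.09e-11, adjusted p = 0.0539 with estimated correlation). Of 19 homing and adhesion receptor genes, 5 rose and 0 fell (9 and 0 within the list), with Cxcr3 at 5.34 ± 0.83 and the integrin gene Itgb1 at 3.49 ± 0.72. Homing and adhesion receptor genes averaged 1.40 (camera adjusted p = 4.21e-08, adjusted p = 0.0579 with estimated correlation). Of 24 cytokine and chemokine genes, 5 rose and 0 fell (10 and 0 within the list), with Ccl3 at 4.44 ± 0.84. Cytokine and chemokine genes averaged 1.61 (camera adjusted p = 4.82e-09, adjusted p = 0.0539 with estimated correlation). Of 18 T cell identity genes, 0 rose and 0 fell (4 and 0 within the list), averaging 1.19 (camera adjusted p = 2.04e-06, adjusted p = 0.307 with estimated correlation). Of 18 microglia genes, 14 rose and 0 fell (18 and 0 within the list), averaging 3.94 (camera adjusted p = 3.82e-45, adjusted p = 0.0539 with estimated correlation). Of 14 natural killer cell genes, 3 rose and 0 fell (3 and 0 within the list), averaging 1.34 (camera adjusted p = 8.21e-05, adjusted p = 0.0579 with estimated correlation).

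Of 24 type I interferon response genes, 1 rose and 0 fell (5 and 0 within the list), averaging 1.80 (camera adjusted p = 2.04e-10, adjusted p = 0.102 with estimated correlation). Of 21 dissociation stress and immediate early genes, 3 rose and 0 fell (8 and 0 within the list), averaging 1.55 (camera adjusted p = 1.72e-10, adjusted p = 0.193 with estimated correlation). Of 13 erythroid and platelet genes, 0 rose and 4 fell (0 and 4 within the list), averaging -2.60 (camera adjusted p = 3.04e-09, adjusted p = 0.0539 with estimated correlation). Camera called the naive and recirculating T cell, T cell receptor activation, glycolysis and hypoxia, oxidative phosphorylation, monocyte and macrophage, neutrophil, dendritic cell and MHC class II, neuron and astrocyte lists. Their mean differences were -0.97 to 1.48 (adjusted p = 1.05e-07 to 0.0360, adjusted p = 0.0740 to 0.536 with an estimated correlation). The proliferation, cholesterol synthesis, extracellular matrix and wound repair, B cell, CD4 and regulatory T cell, endothelial and mural and oligodendrocyte lineage lists did not pass (camera adjusted p = 0.270 to 0.946). Mean and test, or mean and median, differed in sign for the extracellular matrix and wound repair, CD4 and regulatory T cell and endothelial and mural lists. In all, limma called 151 genes higher and 8 lower at day 30 than in blood. The count was 11 (7 higher and 4 lower) with median centring, 276 (251 higher and 25 lower) with unscaled CPM and 313 (257 higher and 56 lower) by DESeq2. It was 58 in a fit on the 2 groups alone and 87 without day 30 brain 1. With the library background term 70 (63 higher and 7 lower) were called, and 35 (30 higher and 5 lower) in the high background libraries alone. With the term the glycolysis and hypoxia, oxidative phosphorylation, neutrophil, dendritic cell and MHC class II and neuron lists no longer passed (adjusted p = 0.0769 to 0.633), and in the high background libraries alone the glycolysis and hypoxia, neutrophil and neuron lists (adjusted p = 0.245 to 0.470).

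**Figure D3:**
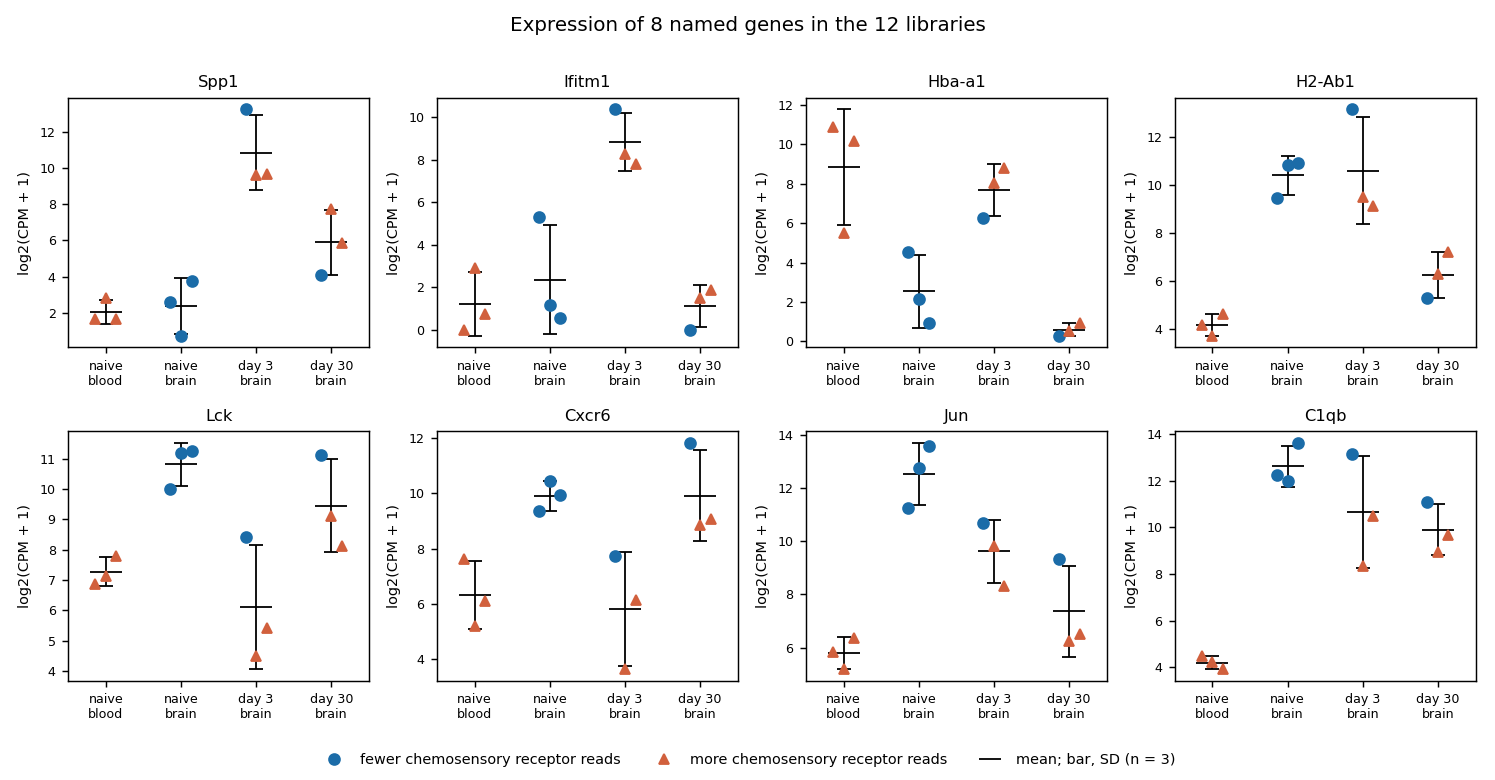
Expression as log2(CPM + 1) of 8 genes per library, by group. Circles are libraries with fewer and triangles with more chemosensory receptor reads, the line is the group mean and the bar the SD (n = 3). Spp1 lay at 3756 ± 5124 CPM at day 3 and 3.44 ± 2.25 CPM in blood.

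Across the 3 brain groups, 75 genes were higher than in blood in each and 0 were lower in each. Ranked by their smallest difference, the leading shared genes included Ly6a, C1qb, Reep5, Siglech, S100a4, a calcium-binding protein gene, Ctsz, Tyrobp, a signalling adaptor of myeloid and natural killer cells, Egr1 and P2ry12. Independent lists of the same sizes would share 0.109 higher genes. Unchanged groups simulated against the same blood libraries shared 18.3 on average and at most 32, with 0.490 on average for lower genes, so part of the excess can come from the shared controls. The overlap was 114 (108 higher and 6 lower) with quantile normalization, 164 (159 higher and 5 lower) by DESeq2, 157 (151 higher and 6 lower) with unscaled CPM, 3 (3 higher and 0 lower) with median centring and 23 (23 higher and 0 lower) with the library background term. Leaving out single libraries gave 125 without day 3 brain 2.

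Over all 4 groups, 1042 genes differed by the limma F test at an adjusted p under 0.05. The count was 684 with quantile normalization and 237 with the library background term. Leaving out single libraries gave 608 without naive brain 3, 1579 without day 30 brain 1.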

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

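The tests of library background, of RNA from microglia in naive brain, of a fixed mixture of other cells and of day 3 brain 2 alone were chosen only after the result was seen. The effects at day 3 and day 30 against naive brain differed from each other, tested as day 30 minus day 3 (log2), for genes named in either comparison that passed in at least 1 of them. Higher at day 30 were Cd2 (3.48), Lck (3.35), Cd27 (3.78), Xcl1 (3.96), Nkg7 (3.54), Cxcr6 (4.09) and Inpp4b (3.25). Haemoglobin genes were lower, with Hba-a1 (-7.10), Hba-a2 (-7.10), Hbb-bt (-5.35) and Hbb-bs (-6.88). So were the MHC class II genes H2-Ab1 (-4.34), H2-DMb1 (-4.65) and H2-Eb1 (-4.20). The other genes lower at day 30 were Spp1 (-4.96), Apoc2 (-6.24), Thbs1 (-6.04), Ifitm1 (-7.70), Ifitm2 (-4.41), Wfdc17 (-4.47), Cd24a (-4.805), Slamf9 (-4.58) and Cxcl2 (-6.98). Of the lists past the threshold with both the preset and the estimated correlation, T cell identity averaged 2.38, and extracellular matrix and wound repair (-1.34), monocyte and macrophage (-1.95), dendritic cell and MHC class II (-2.62) and erythroid and platelet (-2.83) were lower.

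Microglial genes were higher in naive brain than in naive blood, by 6.37 ± 0.98 in the mean of the list. The background (or depth) term rests on 1 low library each at day 3 and day 30. It left 3.91 ± 0.85, but background within a class stays open. RNA from microglia may be a source, as 18 of 18 genes of the list passed in the higher direction and C1qb reached 7139.9 ± 4725 CPM against 17.8 ± 3.78 CPM, though a sort for CD8 should remove such cells. The list took 2.24 to 5.32% of reads in naive brain and 0.0732 to 0.109% in blood, and 1 of its 18 genes is in another list. How many of these genes CD8 T cells of the brain express themselves was not tested, so a difference between the tissues stays open.

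Genes of T cell identity were lower at day 3 than in naive brain, with a difference of -3.06 ± 0.76 in the mean of the list. The background term left -1.71 ± 0.46, but background within a class stays open. A lower share of T cells among otherwise unchanged cells would raise every other type alike, but the monocyte and macrophage list moved 3.41 ± 0.65 above the microglia list. Without day 3 brain 2, the library with the fewest reads on these genes, the mean was still -2.39. A larger share of monocytes and macrophages, which the sort should remove (Spp1 at 3756 ± 5124 CPM), and a change within the T cells may each contribute, and both stay open as untested effects of the injury.

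Stress and immediate early genes were lower at day 30 than in naive brain, with a difference of -2.97 ± 0.84 in the mean of the list. The background term left -1.56 ± 0.59, but background varied within a class (164 to 881 unscaled CPM in naive brain) and stays open. The list did not pass with an estimated correlation, with the term (adjusted p = 0.169) or without it (adjusted p = 0.109). Less RNA from microglia at day 30 remains a candidate explanation: the stress score minus the microglia score differed by -0.55 ± 0.56, within its error. The stress list took 1.84 to 3.92% of reads in naive brain and 0.3995 to 1.06% at day 30, beside 2.24 to 5.32% and 0.673 to 1.33% for the microglia list. Effects of tissue preparation and of the month after stroke were not tested and stay open.

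The 6 libraries of 2 groups can be split in 10 ways, too few for a share under 0.05. The real split and the highest other gave 160 and 0 genes for day 3 against naive brain, 50 and 216 for day 30 against naive brain, and 57 and 7 for day 30 against day 3. Against blood they gave 1696 and 0 for naive brain, 264 and 0 for day 3, and 159 and 1 for day 30. As many genes as in the real split came from 2 splits for day 30 against naive brain and from 1, the real one, in each other comparison. The split with 216 genes joined 3 low background libraries (day 30 brain 1, naive brain 2 and 3), as did some with 0 genes. With the background term day 30 against naive brain had 0 genes by limma (726 at an unadjusted p under 0.05). For day 30 against day 3, the 3 other splits that part all 3 pairs of equal numbers gave 0 genes. Of 100 splits of all libraries, 2 gave as many genes as the F test over 4 groups (1042, highest other 1415) and 2 as many shared by the 3 brain groups against blood (75, highest other 98). Of 100 splits of the brain libraries, 2 gave as many shared by day 3 and day 30 (7, highest other 20). These splits take the libraries as exchangeable and do not keep the pairs of day 3 and day 30. As libraries differ in background, the splits cannot decide on chance for these 3 counts. The shared 7 also lie below the 8.13 that unchanged groups with the same controls gave on average. The split with 1415 genes set 3 and 2 low background libraries into 2 of its 4 groups and none into the others, so it follows library background.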

How the results depend on the processing

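Some tests were chosen after the data were seen. They use the background term, 1 background class alone, unscaled CPM or the block within day 3 and day 30. Counts of genes are given in the order day 3 against naive brain, day 30 against naive brain, day 30 against day 3, naive brain, day 3 and day 30 against blood, the overlap of day 3 and day 30, the overlap of the 3 brain groups, and the F test over 4 groups. As reported they were 160, 50, 57, 1696, 264, 159, 7, 75 and 1042. The counts became 44, 2, 31, 1377, 216, 122, 0, 68 and 723 with a pseudocount of 0.1 and 184, 43, 62, 1727, 230, 94, 9, 49 and 1019 with 5. They came to 45, 1, 24, 1322, 186, 92, 0, 53 and 672 without a filter and 129, 5, 44, 1747, 243, 124, 1, 66 and 956 with a stricter one. The counts were 5, 2, 8, 2894, 75, 11, 2, 3 and 791 with median centring, 56, 12, 134, 704, 601, 179, 4, 114 and 684 with quantile normalization and 225, 119, 265, 1563, 573, 276, 19, 157 and 1104 with unscaled CPM. Library quality weights gave 2104, 256, 97, 4169, 182, 122, 139, 56 and 2634 and a robust spread estimate 184, 63, 66, 1815, 282, 174, 13, 82 and 1138. The library background term gave 5, 0, 140, 35, 220, 70, 0, 23 and 237, with 726 genes for day 30 against naive brain at an unadjusted p under 0.05. Without the F test, the first 8 were 17, 6, 35, 1177, 286, 143, 0, 86 by edgeR and 1000, 240, 167, 3842, 575, 313, 127, 164 by DESeq2. Fits on the 2 groups compared alone gave 176, 0, 91, 1256, 359, 58 for the first 6, with 1919 genes for day 30 against naive brain at an unadjusted p under 0.05. Asking as well for an absolute log2 difference of 1 left the 6 counts reported as they were. In the low background libraries the first 3 were 0, 0, 0 (1018, 1126, 1149 at an unadjusted p under 0.05) and their overlap 0. In the high background libraries day 30 against day 3, day 3 against blood and day 30 against blood gave 15, 135 and 35. Leaving out 1 library at a time, the ranges were 22 to 666, 1 to 532, 26 to 115, 768 to 2124, 139 to 391, 87 to 213, 0 to 59, 50 to 125, 608 to 1579. A library left alone in its group is assumed to vary like the other groups. Fits without libraries or on 2 groups hold fewer libraries, and the filters change how many genes are tested. Otherwise the cause was not tested.

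With the replicate number as a block over all libraries the counts were 314, 121, 115, 1944, 396, 296, 37, 145 and 1405, and with the block within day 3 and day 30 their comparison gave 146. Beside the calls named in the report, for named genes and lists the block within these groups added Dusp2 and Cd8b1 (adjusted p = 0.0253 and 0.0240), and neither block changed another of their calls in that comparison. In the other comparisons same-numbered libraries correlated at -0.421 to 0.149. In none of the 6 comparisons did every library correlate best with its own number, so each block is only a hint.

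Over 162 list tests an estimated correlation ended most calls (92). It kept 1 of 6 T cell identity, 1 of 4 cytokines and chemokines, 1 of 4 erythroid and platelet, 2 of 3 extracellular matrix and wound repair, 2 of 6 microglia, 2 of 5 monocyte and macrophage, 2 of 5 dendritic cell and MHC class II, and 0 of each other list. Other settings ended or turned calls of these lists. Quantile normalization kept 0 of 2 proliferation, 0 of 5 oxidative phosphorylation and 0 of 1 B cell, 2 of 4 cholesterol synthesis and 2 of 4 neutrophil, 3 of 5 T cell receptor activation, 3 of 5 glycolysis and hypoxia and 3 of 5 neuron. With unscaled CPM there were 1 of 2 proliferation, 2 of 4 cholesterol synthesis and 2 of 4 neutrophil, 3 of 5 oxidative phosphorylation, with median centring 0 of 1 B cell, 1 of 2 proliferation, and with the stricter filter 0 of 2 proliferation, 2 of 4 cholesterol synthesis. The background term kept 0 of 2 proliferation, 0 of 5 glycolysis and hypoxia, 0 of 1 B cell and 0 of 5 neuron, 1 of 5 oxidative phosphorylation, 2 of 4 type I interferon response, 2 of 4 cholesterol synthesis and 2 of 4 neutrophil, 3 of 5 tissue-resident memory and 3 of 5 T cell receptor activation. Together with an estimated correlation it kept 1 of 5 naive and recirculating T cell, 1 of 5 tissue-resident memory, 1 of 6 dissociation stress and immediate early, 1 of 4 erythroid and platelet, 2 of 5 cytotoxic effector, 2 of 5 inhibitory receptor and exhaustion, 2 of 5 homing and adhesion receptors, 2 of 3 extracellular matrix and wound repair, 2 of 3 natural killer cell, 2 of 5 dendritic cell and MHC class II, 3 of 6 T cell identity, 3 of 4 cytokines and chemokines, 3 of 6 microglia, 3 of 5 monocyte and macrophage, and 0 of each other list. The single B cell call was lost (0 kept) with a pseudocount of 0.1, no filter, median centring, quality weights, the background term and either class of libraries alone. With single libraries left out, 0 to 2 of 2 proliferation, 3 to 5 of 5 oxidative phosphorylation, 2 to 4 of 4 cholesterol synthesis, 2 to 4 of 4 neutrophil, 0 to 1 of 1 B cell, 1 to 3 of 3 natural killer cell, 3 to 5 of 5 neuron, 0 to 1 of 1 astrocyte calls were kept.

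Some directions turned, given as list means relative to all genes or as log2 differences of single genes. With quantile normalization, in naive brain against blood Ptprc turned to -1.445, naive and recirculating T cell to -1.13 and oxidative phosphorylation to -0.0147. In day 3 against naive brain oxidative phosphorylation turned to 0.0410. In day 30 against naive brain T cell identity turned to 0.0859 and oxidative phosphorylation to 0.24. With unscaled CPM, in naive brain against blood Ptprc turned to -1.075 and naive and recirculating T cell to -0.11. The background term moved more, and in naive brain against blood Cd2 turned to -0.52, Eno1 to -0.0555, Atp5b to -0.0247, T cell identity to -0.19, naive and recirculating T cell to -1.22, proliferation to -0.39, type I interferon response to -0.49, glycolysis and hypoxia to -0.12 and oxidative phosphorylation to -0.27. In day 3 against naive brain type I interferon response turned to 1.08, glycolysis and hypoxia to 0.33 and neuron to -0.0482. In day 30 against naive brain T cell identity turned to 0.67, naive and recirculating T cell to 0.0743, cytotoxic effector to 0.56, tissue-resident memory to 0.72, T cell receptor activation to 0.14, proliferation to 0.17, cytokines and chemokines to 0.0573, glycolysis and hypoxia to 0.21 and oxidative phosphorylation to 0.57. In day 3 against blood oxidative phosphorylation turned to -0.45. In the low background libraries alone, in day 3 against naive brain T cell receptor activation turned to 0.31, type I interferon response to 1.51, glycolysis and hypoxia to 0.59, oxidative phosphorylation to 0.18, microglia to 0.22 and neuron to -0.11. In day 30 against naive brain T cell identity turned to 0.26, cytotoxic effector to 0.34 and oxidative phosphorylation to 0.21. In day 30 against day 3 type I interferon response turned to -0.37. In the high background libraries alone, in day 30 against day 3 microglia turned to 0.21. In day 3 against blood oxidative phosphorylation turned to -0.62. With quality weights, in day 30 against day 3 microglia turned to 0.31. In 3 cases the mean kept its sign, near 0, and only the direction of the camera test turned: cytotoxic effector in day 30 against naive brain (-0.0756, quantile normalization), oxidative phosphorylation in day 30 against day 3 (0.0384, the low background libraries) and cholesterol synthesis in naive brain against blood (0.0618, the background term). Ranges without single libraries that crossed 0 were found for the proliferation list (-1.30 to 0.16, turned without naive brain 3) in day 30 against naive brain; dissociation stress and immediate early list (-1.30 to 0.21, turned without day 3 brain 1), type I interferon response list (-0.0503 to 1.44, turned without day 3 brain 2), glycolysis and hypoxia list (-0.625 to 0.65, turned without day 3 brain 1) and microglia list (-1.34 to 0.77, turned without day 30 brain 2 and day 3 brain 1) in day 30 against day 3; oxidative phosphorylation list (-0.62 to 0.74, turned without day 3 brain 1) in day 3 against blood. The cause was not tested.

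Among the tests of named genes, 169 calls were lost with median centring, 73 with quantile normalization, 12 with unscaled CPM, 83 by edgeR, 38 by DESeq2 and 165 with the background term, in the same direction. Depth limits genes near the floor, since the shallowest library held 1104490 reads, and the 2 deepest are of naive brain.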

Other observations

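The tests of list scores minus the T cell identity score were chosen only after the results on that list were seen. Set against T cell identity in the same library (log2, mean ± SD, n = 3), the type I interferon response score was -0.93 ± 0.37 at day 3, -2.97 ± 0.07 at day 30, -3.86 ± 0.81 in naive brain and -3.58 ± 0.63 in blood. The cytotoxic effector score, of genes for granzymes and killing, was -0.54 ± 0.30 at day 3, -1.59 ± 0.18 at day 30, -1.62 ± 0.33 in naive brain and -2.43 ± 0.46 in blood by the same measure. For tissue-resident memory it was -0.46 ± 0.44 at day 3, -1.88 ± 0.30 at day 30, -2.33 ± 0.36 in naive brain and -2.81 ± 0.43 in blood. The naive and recirculating T cell score, which includes genes of lymph node homing, lay at -0.39 ± 0.38 at day 3, -1.79 ± 0.48 at day 30, -1.64 ± 0.13 in naive brain and 0.06 ± 0.17 in blood. Proliferation lay at -1.74 ± 0.78 at day 3, -4.58 ± 0.24 at day 30, -4.62 ± 1.27 in naive brain and -3.60 ± 0.62 in blood. In exact permutation tests of these and the inhibitory receptor and exhaustion score in 6 comparisons, the smallest p was 0.10, the smallest that 3 against 3 libraries can give, and none passed (smallest adjusted p = 0.157). The day 3 values rest on a T cell identity score that was itself lower there, and the share of other cells was not separated from it.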
